A study of Mus musculus with 6 samples.

How the data were processed

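RNA of isolated mouse islets was measured by sequencing in 6 libraries, 2 each of wild type (WT), of βRapKO (KO) and of βRapKO islets given Dnmt3a by lentivirus (KO+DNMT3A), from mice aged 8 weeks. Poly-A libraries were made with a TruSeq kit from RNA purified with an RNeasy Micro kit, per the labels' protocols. The deposited values are FPKM per gene, per the file headers. HISAT2 2.0.4, StringTie 1.3.0, edgeR and the mm10 genome are named, per the submitters' processing notes, which do not say what each did or in which order. No counts or read files were at hand, and no column was left out. The deposited column names of the WT and KO libraries contain GFP, which the labels do not explain, and end in the numbers 3 and 6 for WT, 1 and 3 for KO, and 2 and 3 for KO+DNMT3A, in the order of the replicates; what these numbers stand for is not stated.

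The table held 34745 genes, of which 478 had no symbol and 15901 were 0 in all libraries. Gene symbols, types and positions come from GENCODE M21 on GRCm38/mm10, matched by gene identifier. Depth is not stated. It was inferred from genes with a single annotated transcript, whose FPKM values should be whole multiples of the value of 1 fragment; 84.2% to 91.5% of the values up to 20 fragments were whole multiples within 0.01. These inferred depths cover fragments assigned to genes only, and counting error follows from them.

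Genes with at least 1 FPKM in at least 2 libraries were kept, which left 13233. Values were transformed as log2 of FPKM plus 1, and all 6 libraries entered a single limma 3.58.1 fit with a trended, robust empirical Bayes step (R 4.3.3). The 3 comparisons were KO against WT, KO+DNMT3A against KO and KO+DNMT3A against WT. Tests were two-sided, with Benjamini-Hochberg adjustment per comparison at 0.05. Folds refer to values after the pseudocount was added. Before the data were examined, 29 gene lists were written down for beta cell identity, other islet and pancreas cell types, mTOR complexes, DNA methylation, Polycomb, metabolism, stress, the cell cycle and imprinting, and ribosomal and mitochondrially encoded genes were taken from the annotation. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data. A list with too few measured genes was not tested. The change in opposite directions was measured by the covariance and correlation of the fold changes of the first 2 comparisons, set beside 100 simulated sets of groups with no effect, because both share the KO libraries.

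Named genes followed a rule fixed before the data were examined. It names Rptor and Dnmt3a, the 5 higher and 5 lower genes with the smallest unadjusted p per comparison where none passed (groups not overlapping, mean of at least 2 FPKM), up to 4 members with the smallest p of each list described, and Ins1, Ins2, Gcg, Sst, Mafa, Ucn3, Slc2a2, Ldha and Slc16a1. Iapp, Nkx6-1, C1qa and Fcer1g were added after their values were seen.

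The gene test was tested on simulated data made from the libraries' means, for KO against WT over 13233 genes. At the spread of these libraries it recovered 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 0 of 50 changed 8-fold and 0 of 50 changed 16-fold. At 0.1 of that spread it recovered 48, 49, 50 and 50 of 50. A simulated list of 20 genes moved by 1.5 on the log2 scale was called by camera with an adjusted p of 4.57e-14, and 0 other lists were, of 28 tested. The simulated genes were drawn independently, so this does not show how often camera calls lists whose genes move together. In the real lists the estimated correlation was, for instance, 0.968 for mitochondrially encoded and 0.175 for macrophage genes, against the preset 0.01. The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, median scaling, a fit with no trend, a fit of only the groups compared, a replicate block, an estimated correlation, and each library left out in turn. A fit without both insulin-poor libraries, a crossed replicate block and a replicate block by deposited number were added after the values were seen. The fit without both libraries leaves a single WT and a single KO library, so its spread comes from the KO+DNMT3A libraries alone. Its list calls therefore do not measure how WT or KO libraries vary. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, tests of explanations and figures.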

Results

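Gene expression was measured by RNA sequencing of poly-A RNA from isolated pancreatic islets of C57BL/6 mice aged 8 weeks. The series holds 6 libraries in 3 groups of 2. The WT group comes from wild-type mice. The KO group comes from mice called βRapKO, in which Rptor was deleted in beta cells; Rptor encodes Raptor, the defining subunit of the growth-controlling kinase complex mTORC1. The third group, KO+DNMT3A, comes from βRapKO islets given the DNA methyltransferase Dnmt3a by lentivirus. The values are the authors' FPKM, and no read counts accompany them. The smallest steps between values of genes with a single transcript imply about 244636 fragments in WT replicate 1, 973267 in WT replicate 2, 1426335 and 780504 in KO replicates 1 and 2, and 1920991 and 1117581 in KO+DNMT3A replicates 1 and 2. At these depths 1 fragment on a transcript of 2 kb is worth 2.04 FPKM in WT replicate 1 and 0.26 FPKM in KO+DNMT3A replicate 1. Genes above 0 numbered 10579 in WT replicate 1 and 14073 to 16315 in the other 5 libraries.

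The islets of 2 libraries, WT replicate 1 and KO replicate 2, stood apart in their beta cell transcripts. Ins1 was 647 FPKM in WT replicate 1 and 416 FPKM in KO replicate 2, against 100772 FPKM in WT replicate 2, 119077 FPKM in KO replicate 1, and 65360 and 100107 FPKM in the KO+DNMT3A libraries. Ins1 and Ins2 together held 0.17% and 0.11% of the summed FPKM in these 2 libraries and 16.5% to 30.5% in the others. Iapp, which encodes amylin and was named after its values were seen, as was Nkx6-1, was 512 and 841 FPKM there and 22491 to 54683 FPKM elsewhere. Ucn3, a marker of mature beta cells, was 5.53 and 20.8 FPKM there and 119 to 337 FPKM elsewhere. The beta cell transcription factor gene Nkx6-1 was 43.0 and 49.4 FPKM there and 66.2 to 160 FPKM elsewhere. Gcg, the alpha cell hormone, was 1245 and 2454 FPKM there and lay between 1197 and 1932 FPKM in the other 4. Another islet hormone gene, Sst, was lower in WT replicate 1 than in WT replicate 2. Its log2 fold change of KO against WT was 0.512 without WT replicate 1 and 3.04 without WT replicate 2. Mitochondrially encoded genes took 44.8% and 50.9% of the summed FPKM in these 2 libraries and 16.5% to 26.5% in the others. The rRNA-associated transcripts Gm42418, Gm26917 and Lars2 together took 15.3% and 8.1% there and 2.15% to 4.06% in the others. Each of the 3 comparisons below contains at least 1 of these libraries. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

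**Figure D1:**
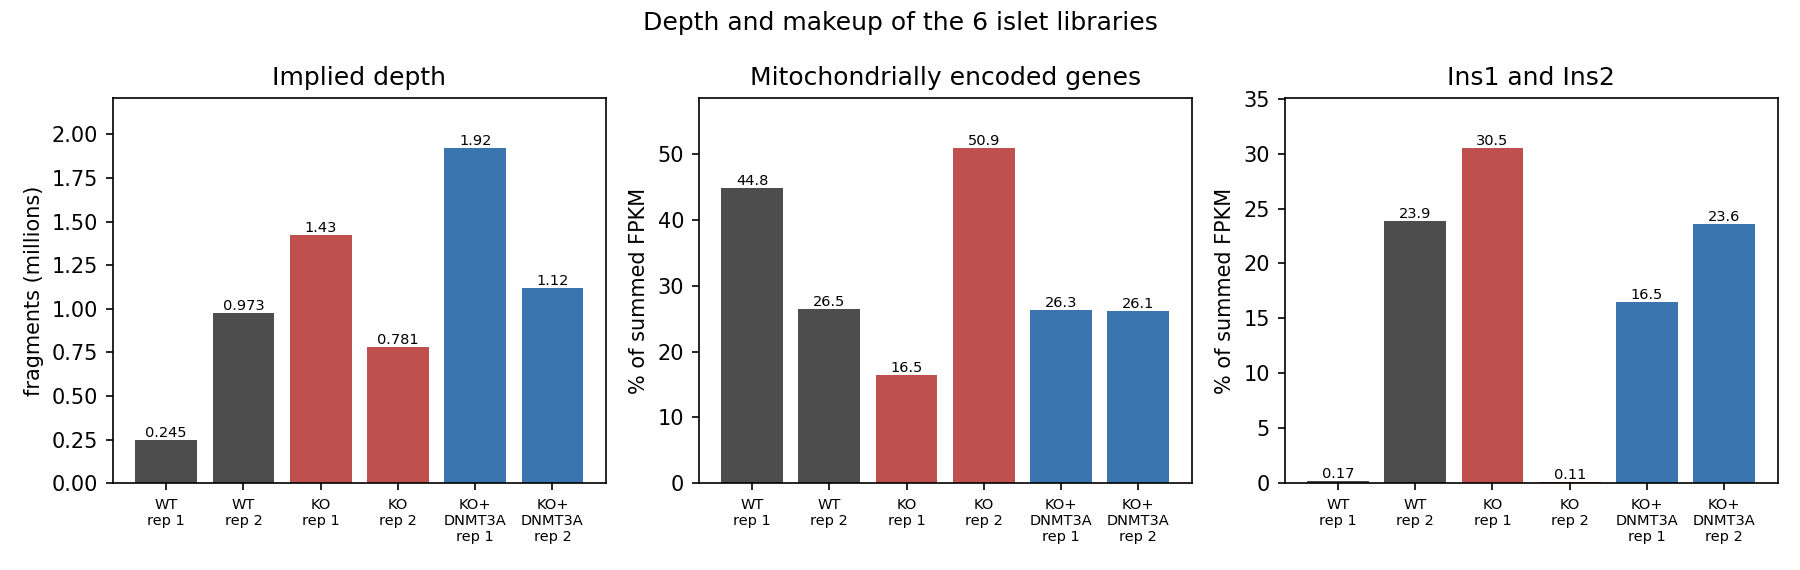
Bars give, for each of the 6 libraries (grey WT, red KO, blue KO+DNMT3A), the implied number of fragments, the percentage of summed FPKM from mitochondrially encoded genes, and the percentage from Ins1 and Ins2. WT replicate 1 and KO replicate 2 had 0.17% and 0.11% of their FPKM in insulin genes, and WT replicate 1 was the shallowest at about 244636 fragments.

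The targeted genes were read first as a check of the labels. Rptor (ENSMUSG00000025583, chromosome 11, 119602905 to 119899576, GRCm38/mm10) was 0.80 and 1.06 FPKM in the libraries labelled WT, 0.38 and 1.51 FPKM in those labelled KO, and 0.71 and 1.93 FPKM in those labelled KO+DNMT3A. If the longest transcript is assumed, these values rest on 1.3 to 14.2 fragments. The log2 fold change of KO against WT was -0.05 with a standard error of 0.58. KO replicate 2 had more Rptor signal than either WT library, so the Rptor value does not support the KO label, and the libraries are called by their labels throughout. A gene-level FPKM counts all exons and all islet cells, so it need not show a deletion of some exons in beta cells. Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443) was 2.94 and 4.43 FPKM in WT, 3.19 and 2.5 FPKM in KO, and 3.62 and 3.8 FPKM in KO+DNMT3A. Its log2 fold change was 0.30 (SE 0.51) for KO+DNMT3A against KO and -0.27 (SE 0.51) for KO against WT. Neither passed (limma adjusted p = 1), and the means of KO+DNMT3A and WT differed by 0.03 on the log2 scale.

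**Figure D2:**
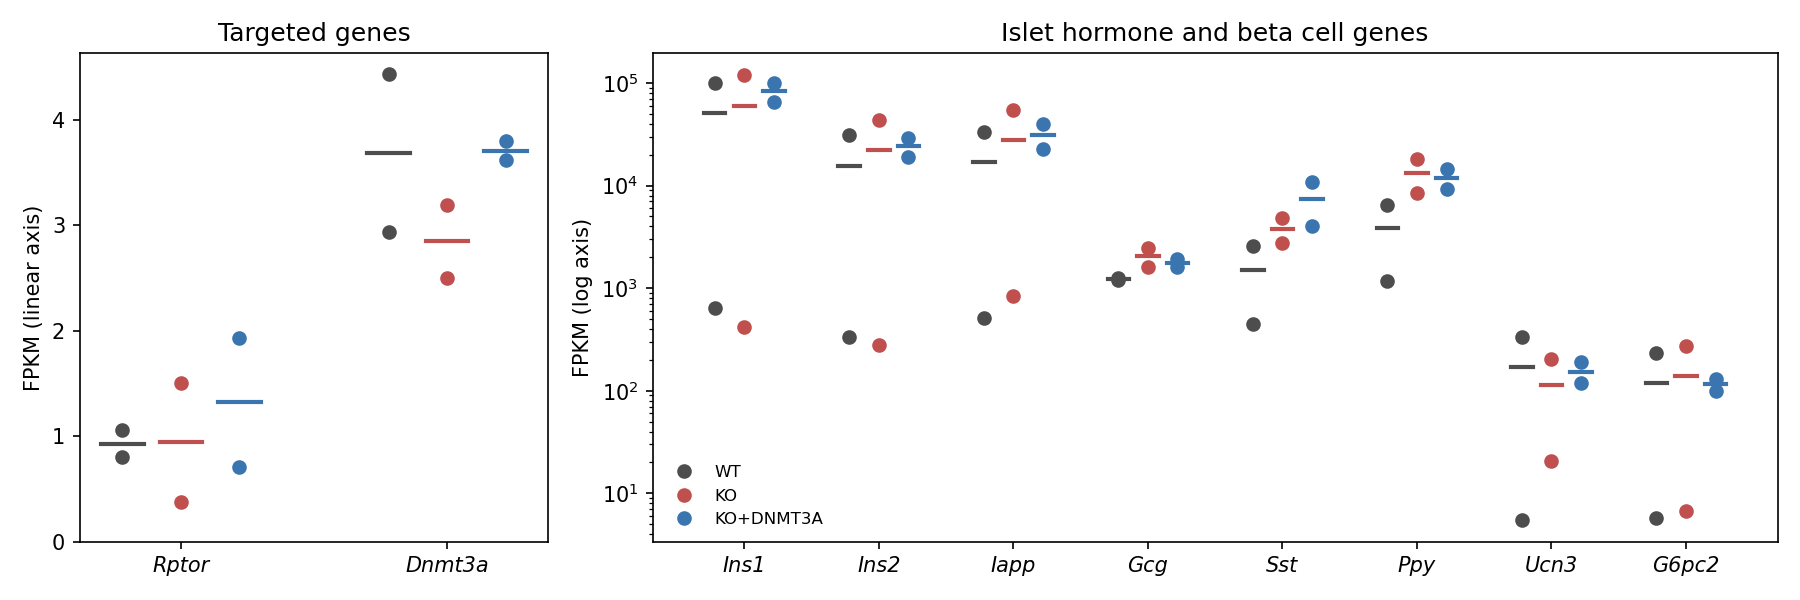
Points give the FPKM of each library and bars the mean of the 2 libraries of a group (grey WT, red KO, blue KO+DNMT3A), on a linear axis for Rptor and Dnmt3a and on a log axis for islet hormone and beta cell genes. Dnmt3a was 3.62 and 3.8 FPKM in KO+DNMT3A and 3.19 and 2.5 FPKM in KO, and Ins1 separated WT replicate 1 and KO replicate 2, at 647 and 416 FPKM, from the other 4 libraries.

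Libraries labelled KO were compared with WT to ask how loss of Raptor from beta cells alters islet transcripts. Genes of the other islet hormone cells and of Schwann cells were shifted higher in KO, and genes of stellate cells and fibroblasts, duct cells, glycolysis, the cell cycle, the cytosolic ribosome and the set normally repressed in mature beta cells were shifted lower. These 8 calls were made by camera with a preset correlation, and with an estimated correlation the adjusted p was 0.959 for each. Of the 14 hormone cell genes, 11 had a higher mean in KO, with a median log2 fold change of 0.45. Pancreatic polypeptide, Ppy, was 13380 ± 7044 FPKM in KO and 3844 ± 3771 FPKM in WT (SD, n = 2). Its relative Pyy was 2951 ± 339 against 1032 ± 736 FPKM, ghrelin, Ghrl, was 7.85 ± 2.37 against 1.13 ± 1.59 FPKM, and the retinol carrier Rbp4 was 53.2 ± 8.65 against 23.7 ± 11.3 FPKM. Somatostatin, Sst, was 3804 ± 1511 against 1502 ± 1496 FPKM, where WT replicate 1 held the lower WT value, and Gcg was 2039 ± 588 against 1221 ± 33.7 FPKM. In the Schwann cell list 7 of 8 genes were higher, with a median of 0.82; Sox10, the glial lineage regulator, was 3.61 ± 2.91 against 0.38 ± 0.54 FPKM.

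Among the genes repressed in mature beta cells, 19 of 23 were lower in KO (median -0.46). The values cover all islet cells, so they need not reflect beta cells. This list shares Pdgfra with the stellate list and Hk1 and Ldha with the glycolysis list, so the calls are not separate. The glutathione transferase gene Mgst1 was 0.90 ± 0.16 against 10.1 ± 10.7 FPKM, the ornithine aminotransferase gene Oat 6.88 ± 1.32 against 17.6 ± 10.02 FPKM, and Fcgrt, which encodes an IgG receptor, 8.56 ± 2.73 against 20.6 ± 7.42 FPKM. Ldha, lactate dehydrogenase A, was 45.4 and 18.1 FPKM in WT and 13.3 and 13.4 FPKM in KO, and Slc16a1, the lactate transporter MCT1, stayed under 1 FPKM in all 4 libraries. In glycolysis 15 of 19 genes were lower (median -0.46), with Eno1 at 7.50 ± 0.24 against 18.3 ± 6.06 FPKM and Tpi1 at 26.1 ± 6.10 against 51.5 ± 21.7 FPKM. Many glycolytic and ribosomal protein genes have processed pseudogenes, and whether reads were shared with them was not tested, so their levels are uncertain. Of the cell cycle genes 14 of 20 were lower (median -0.54), among them the replication helicase gene Mcm3 at 0.45 ± 0.10 against 2.22 ± 0.55 FPKM and the ribonucleotide reductase gene Rrm2 at 1.84 ± 1.14 against 4.27 ± 1.74 FPKM. Stroma genes were lower in 17 of 22 cases (median -0.66) and duct genes in 8 of 12 (median -0.82), where WT replicate 1 held most of the signal: Dcn, decorin, was 194 FPKM there and 19.06 to 24.1 FPKM in WT replicate 2 and both KO libraries, and the duct gene Mmp7 was 639 FPKM there and 2.63 to 4.81 FPKM in the same 3 libraries. Cytosolic ribosomal protein genes were lower in 56 of 79 cases (median -0.27). Beta cell genes had no list call: their median was 0.19 (camera adjusted p = 0.856) with all 6 libraries. The list was called lower without WT replicate 1 (-1.23, adjusted p = 1.22e-05) and higher without KO replicate 2 (1.285, adjusted p = 0.0015). Slc2a2, the glucose transporter GLUT2, was listed at 0 in WT replicate 1 and at 20.7 FPKM in WT replicate 2, against 10.8 and 0.72 FPKM in KO.

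No single gene passed the limma test in KO against WT (0 of 13233, smallest adjusted p = 1). By the same test 240 genes had an unadjusted p under 0.05 where 662 would be expected with no effect. At this spread the test recovered 0 of 50 simulated genes changed 16-fold, so these counts do not show that little changed. All comparisons share this estimate of the spread. Libraries did not group by label: Pearson correlation was 0.719 between the WT libraries and 0.765 between the KO libraries. It was 0.901 between WT replicate 2 and KO replicate 1. The 5 higher genes with the smallest p were the elastase gene Cela1, Pet117, Clybl, the pseudogene Cox20b and Tmsb15b1, and the 5 lower ones were Ms4a4a, Gnb1, Mfap2, Ugt1a7c and the pseudogene Cbx3-ps7; none passed. Cela1 was listed at 0 in both WT libraries and at 8.09 ± 3.35 FPKM in KO (n = 2). Gnb1, a G protein beta subunit gene, was 13.9 ± 5.06 FPKM in WT and 1.90 ± 0.17 FPKM in KO, and Ms4a4a was 10.4 ± 0.91 FPKM in WT and listed at 0 in KO. The list shifts were called by camera with a preset correlation of 0.01, with adjusted p from 0.00528 for the repressed, stellate, glycolysis and cell cycle lists to 0.0363 for the hormone, Schwann and duct lists, and 0.0092 for the ribosome. No member of these lists passed when adjusted over the list alone. Of the acinar list only 3 genes were measured, too few for the list test, and 1 of them, Cela1, passed when adjusted over the list alone. Without WT replicate 1 the medians of the repressed, stellate and duct lists were 0.08, 0.36 and -0.08, and the stellate list was called higher (camera adjusted p = 0.0135). Without KO replicate 2 that of the Schwann list was -0.15, and without KO replicate 1 that of the ribosome was 0.04. The hormone list lost its call without KO replicate 2 (median 0.19, adjusted p = 0.685), without WT replicate 1 (0.40, 0.0558) and without WT replicate 2 (0.545, 0.323). The duct list lost it without either insulin-poor library, and the ribosomal list without WT replicate 1, WT replicate 2 or KO replicate 1. The glycolysis list lost its call without WT replicate 2 (median -0.238), and the cell cycle list without WT replicate 2 or KO replicate 1. With both insulin-poor libraries left out only glycolysis (-0.57) and the ribosome (-0.52) kept the call among the 8 lists. That fit compares 1 KO library with 1 WT library, so its calls do not measure the spread within either group. Medians in it were -0.848 for mitochondrially encoded, 0.47 for endothelial and 0.437 for ER folding genes.

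Libraries labelled KO+DNMT3A were compared with KO, which by the labels asks what added Dnmt3a does in βRapKO islets; the Rptor and Dnmt3a values did not show either change. Macrophage genes were lower in KO+DNMT3A. Of the 16 measured genes 14 were lower, with a median log2 fold change of -0.85 (camera adjusted p = 3.59e-12, and 0.675 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid cells, was 13.6 ± 0.96 FPKM in KO+DNMT3A and 44.3 ± 11.2 FPKM in KO (SD, n = 2). The complement genes C1qb and C1qc were 22.04 ± 1.39 against 71.6 ± 16.3 FPKM and 4.23 ± 0.50 against 14.7 ± 6.45 FPKM. Laptm5, a lysosomal protein gene of blood cells, was 2.47 ± 0.51 against 6.96 ± 0.33 FPKM. These 4 genes had an unadjusted p under 0.05 and did not pass after adjustment. The macrophage shift kept its direction and its call without each library in turn (medians -1.18 to -0.489) and with both insulin-poor libraries left out (-1.18).

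**Figure D3:**
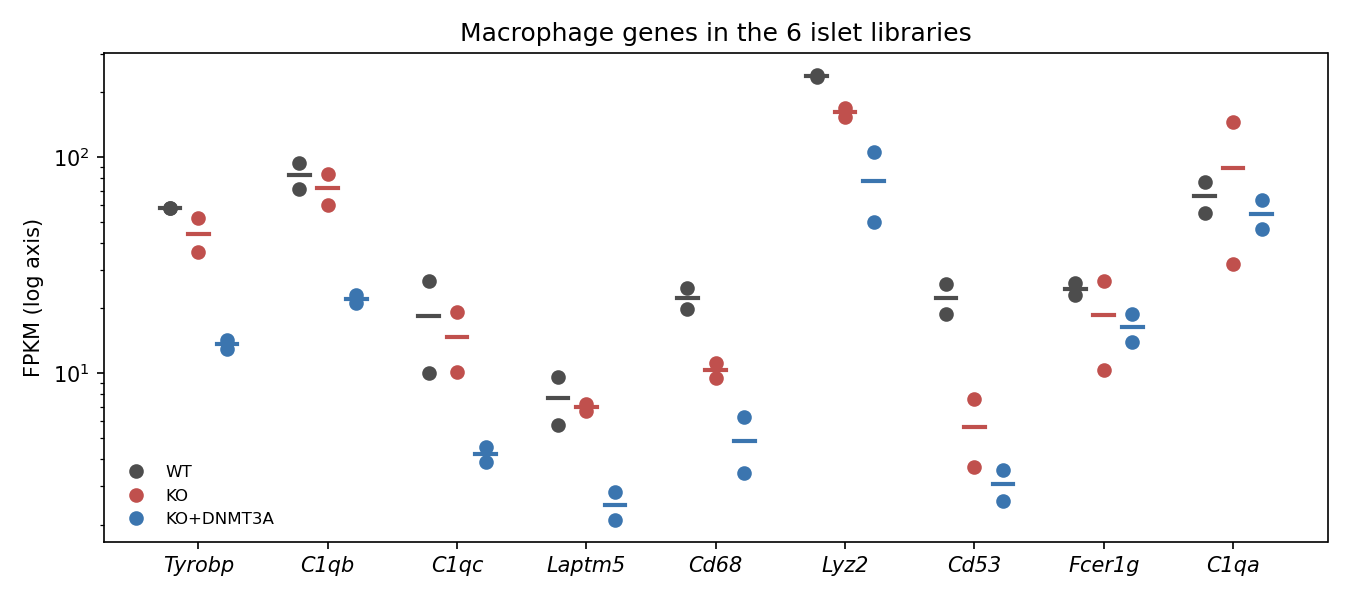
Points give the FPKM of 9 macrophage genes in each library on a log axis, and bars the mean of the 2 libraries of a group (grey WT, red KO, blue KO+DNMT3A). Tyrobp was 12.9 and 14.3 FPKM in KO+DNMT3A and 36.3 to 58.3 FPKM in the other 4 libraries, while C1qa and Fcer1g, named after their values were seen, overlapped between groups.

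Duct, stellate, Schwann and mature beta cell lists were also called between KO+DNMT3A and KO with the preset correlation, and each had an adjusted p of 0.982 with an estimated correlation. All 12 duct genes were higher in KO+DNMT3A (median 1.08, camera adjusted p = 0.00155, and 0.982 with an estimated correlation). KO+DNMT3A replicate 1 carried most of this: Krt19 was 94.6 FPKM there, 2.30 FPKM in replicate 2, and 2.70 and 1.10 FPKM in KO. Clu was 259 FPKM there and 29.0 FPKM in replicate 2, against 33.7 and 12.7 FPKM in KO. Stellate and fibroblast genes were lower in 15 of 22 cases (median -0.31, camera adjusted p = 0.000227, and 0.982 with an estimated correlation). Fibronectin, Fn1, was 4.65 ± 2.23 against 13.9 ± 4.90 FPKM and Lum 6.15 ± 4.43 against 15.1 ± 3.93 FPKM. Schwann cell genes were lower in 6 of 8 cases (median -0.61, camera adjusted p = 0.000241, and 0.982 with an estimated correlation). The nerve growth factor receptor gene Ngfr was 51.7 FPKM in KO replicate 2 and 10.4 FPKM in KO replicate 1, against 11.03 and 2.08 FPKM in KO+DNMT3A. Mature beta cell genes were higher in 25 of 26 cases (median 0.87, camera adjusted p = 0.00668, and 0.982 with an estimated correlation). Here KO replicate 2 decided the value: without it the median was -0.14. Mafa, a transcription factor gene of mature beta cells, was 0.96 and 2.49 FPKM in KO+DNMT3A and 0.65 and 0 FPKM in KO, Ucn3 was 189 and 119 FPKM against 205 and 20.8 FPKM, and Slc2a2 was 6.72 and 8.03 FPKM against 10.8 and 0.72 FPKM.

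Ribosomal protein, endothelial, cell cycle and mitochondrially encoded lists were also called lower, with medians of -0.02, -0.07, -0.03 and -0.21 and camera adjusted p of 0.00377, 0.0415, 0.0452 and 0.0415; with an estimated correlation each had an adjusted p of 0.982. The median of all genes was 0.189 (-0.017 after median scaling), and these lists were lower relative to it. The cell cycle list lost its call whichever library was left out (camera adjusted p from 0.0598 to 0.296), and the mitochondrially encoded list was called lower only without KO replicate 1. With both insulin-poor libraries left out, which leaves a single KO library, the mitochondrially encoded median was 0.635 and the ribosomal median 0.12. No gene passed the limma test (0 of 13233, smallest adjusted p = 1; 147 at an unadjusted p under 0.05). The higher genes with the smallest p were Orm1, Platr26, Lhx1os, Sftpd and Lcn2, none of which passed. Orm1, which encodes an acute-phase plasma protein, was 13.4 and 11.5 FPKM in KO+DNMT3A and listed at 0 in the other 4 libraries. Lcn2, which encodes the siderophore-binding protein lipocalin 2, was 51.2 ± 20.9 against 7.93 ± 9.36 FPKM, and Sftpd, surfactant protein D, was 12.04 ± 4.63 against 1.32 ± 1.87 FPKM (n = 2). The lower ones were Col8a1, Rac1, Mgp, Pdf and Adap2, which also did not pass. Mgp, matrix Gla protein, was 40.8 ± 0.23 against 144.8 ± 30.6 FPKM, and Rac1, a small GTPase gene, was 3.50 ± 2.18 against 15.9 ± 0.72 FPKM. Without KO replicate 2 the Schwann median was 0.05, without KO+DNMT3A replicate 1 the duct median was 0.16, and without KO+DNMT3A replicate 2 the stellate median was 0.07. None of the 9 list calls held with an estimated correlation (adjusted p = 0.675 for macrophages and 0.982 for the others). With both insulin-poor libraries left out 3 of the 9 were still called in the same direction, those of macrophages, duct cells (0.76) and endothelial cells (-0.36). The medians of 4 of the 9 changed sign, among them those of mature beta cell genes, at -0.14, and mitochondrially encoded genes, at 0.635. These calls rest on a single KO library.

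Libraries labelled KO+DNMT3A were also compared with WT, which asks how far the treated islets lie from wild-type ones. Macrophage genes were lower here too, in 13 of 16 cases (median -0.996, camera adjusted p = 1.61e-09, and 0.465 with an estimated correlation). The same 2 KO+DNMT3A libraries enter the comparison with KO, so this is not an independent repeat. Cd68, a macrophage lysosomal protein gene, was 4.88 ± 2.005 FPKM in KO+DNMT3A and 22.3 ± 3.59 FPKM in WT (SD, n = 2). Tyrobp was 13.6 ± 0.96 against 58.1 ± 0.22 FPKM, C1qb 22.04 ± 1.39 against 82.3 ± 16.3 FPKM, and lysozyme 2, Lyz2, 77.7 ± 39.0 against 236.6 ± 3.10 FPKM. Cell cycle genes were lower in 18 of 20 cases (median -0.33, adjusted p = 7.53e-06, and 0.465 with an estimated correlation), among them Rrm2 at 0.59 ± 0.15 against 4.27 ± 1.74 FPKM, the topoisomerase gene Top2a at 0.37 ± 0.17 against 2.34 ± 1.16 FPKM and the proliferation marker Mki67 at 0.38 ± 0.09 against 2.39 ± 0.51 FPKM. Such values correspond to few fragments in WT replicate 1. Both lists kept direction and call without each library in turn, with medians of -1.66 to -0.699 for macrophages and -0.853 to -0.13 for the cell cycle.

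With an estimated correlation none of the remaining 8 calls held (adjusted p = 0.927 for each). Stroma genes were lower in 20 of 22 cases (median -0.87, camera adjusted p = 3.25e-09, and 0.927 with an estimated correlation). Lum was 6.15 ± 4.43 against 37.9 ± 35.5 FPKM and the collagen gene Col6a1 16.0 ± 3.97 against 55.4 ± 45.4 FPKM. Ribosomal protein genes were lower in 61 of 79 cases (median -0.33, adjusted p = 5.17e-07), endothelial genes in 10 of 12 (median -0.41, adjusted p = 0.0012), glycolysis genes in 12 of 19 (median -0.23, adjusted p = 0.0263) and all 13 mitochondrially encoded genes (median -0.52, adjusted p = 0.00477); the estimated-correlation p was 0.927 for these 4 lists too. Genes repressed in mature beta cells were lower in 17 of 23 cases (median -0.42, camera adjusted p = 5.99e-05, and 0.927 with an estimated correlation). Among them Fcgrt was 5.89 ± 3.96 against 20.6 ± 7.42 FPKM. Ldha was 20.8 and 4.29 FPKM against 45.4 and 18.1 FPKM. Insulin processing and exocytosis genes were higher in 26 of 28 cases (median 0.93, adjusted p = 0.00211) and mature beta cell genes in 24 of 26 (median 1.04, adjusted p = 0.0244), again at 0.927 with an estimated correlation. Chgb, chromogranin B, was 4083 and 1556 FPKM in KO+DNMT3A and 71.6 and 1208 FPKM in WT, and Neurod1, an endocrine transcription factor gene, 205 and 179 FPKM against 47.9 and 123 FPKM. These beta cell values follow WT replicate 1: without it the median of the mature beta cell list was -0.40 and that of the processing list -0.01.

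In KO+DNMT3A against WT no gene passed the limma test (0 of 13233, smallest adjusted p = 0.997), and 379 had an unadjusted p under 0.05, of which 293 were higher and 86 lower. This excess of higher genes depended on scaling, with 146 higher and 169 lower after quantile normalization and 221 and 140 after median scaling. The median log2 fold change of all genes was 0.228 here, and 0.014 after median scaling. Orm1, Platr26, Cela1, Dyrk2 and Tmsb15b1 were the higher genes with the smallest p, and Cd53, Mfap2, Gnb1, Ms4a4a and Ube2c the lower ones; none passed. The leukocyte membrane protein gene Cd53 was 3.08 ± 0.72 FPKM in KO+DNMT3A and 22.3 ± 4.90 FPKM in WT, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 0.48 ± 0.68 against 6.83 ± 3.41 FPKM (n = 2). Without WT replicate 1 the medians of the repressed, endothelial and stellate lists were 0.22, 0.11 and -0.08. Without KO+DNMT3A replicate 2 those of the repressed and glycolysis lists were 0.089 and 0.28, and without WT replicate 2 that of glycolysis was 0.27. The ribosomal list lost its call without KO+DNMT3A replicate 1 (median -0.02, camera adjusted p = 0.152), and the mitochondrially encoded list without that library (-0.456, 0.101) and without WT replicate 1 (-0.10, 0.785). None of the 10 list calls held with an estimated correlation (adjusted p = 0.465 for macrophages and the cell cycle and 0.927 for the others). With both insulin-poor libraries left out 4 of the 10 were called in the same direction. These were macrophages (-0.86), glycolysis (-0.43), the cell cycle (-0.53) and the ribosome (-0.33). The medians of 4 of the 10 changed sign, among them that of mature beta cell genes, which was then -0.40. The hormone cell median was 0.551. The duct median was 1.133, against 0.202 with all libraries. This fit rests on a single WT library.

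**Figure D4:**
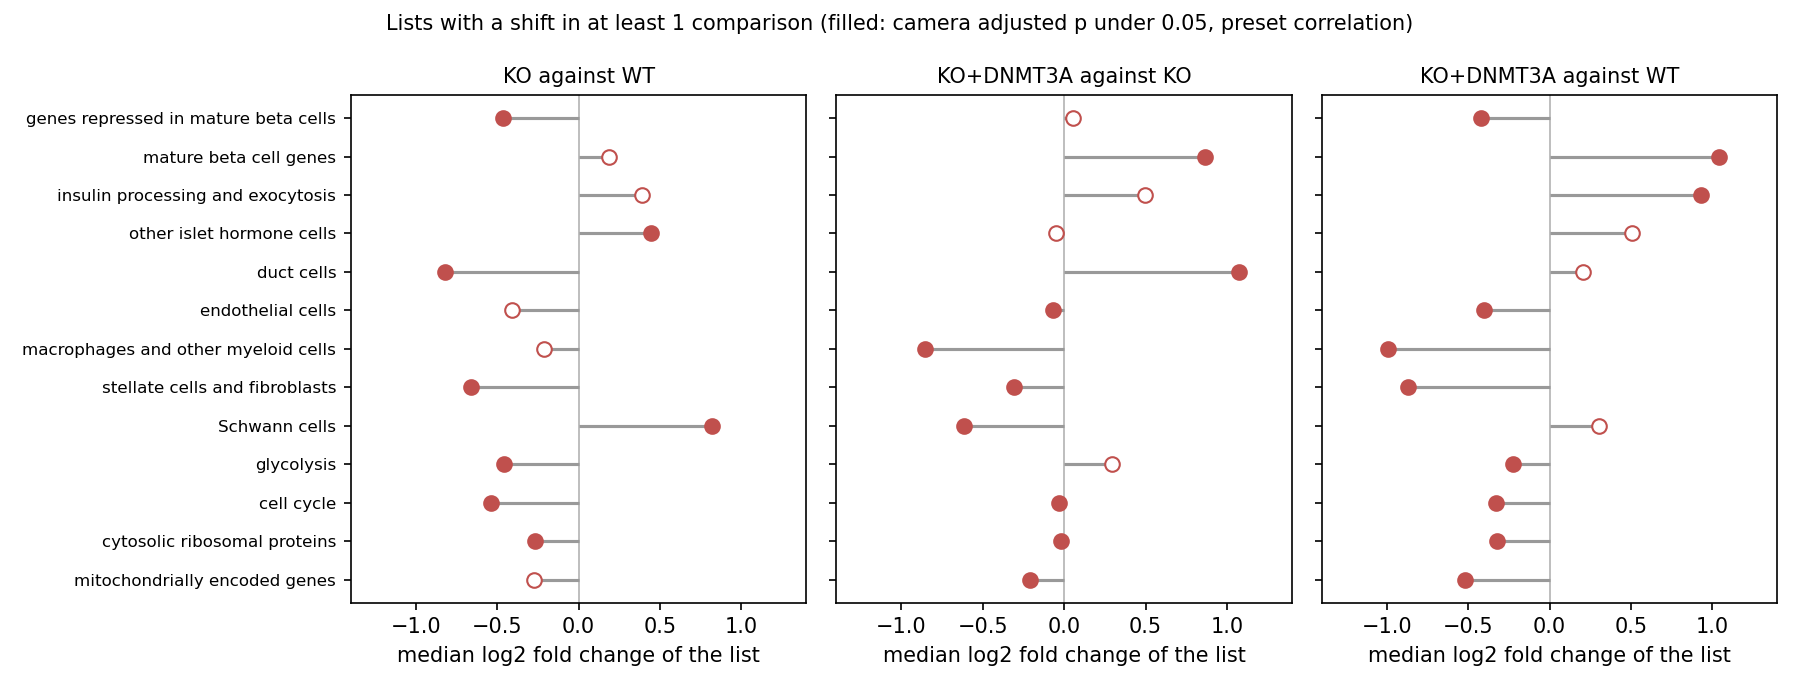
Points give the median log2 fold change of each gene list in the 3 comparisons, for the lists called in at least 1 of them. Filled points passed camera with a preset correlation, and none passed with an estimated correlation. Macrophage genes had medians of -0.85 against KO and -0.996 against WT in the KO+DNMT3A libraries.

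Whether KO+DNMT3A against KO moved genes opposite to KO against WT was examined across the 13233 genes, which are not independent replicates. No gene was called in opposite directions. The fold changes of the 2 comparisons had a Pearson correlation across genes of -0.27 and a covariance of -0.0947. Both comparisons contain the same KO libraries, which gives a negative value with no effect at all: in 100 simulated sets of unchanged groups the correlation averaged -0.50 and the covariance -0.331 (lowest -0.378, highest -0.305). With all 6 libraries the observed covariance was less negative than in these sets. The sets drew each gene independently and gave it the same spread in all 6 libraries. Their range is therefore not a measure of chance for these libraries, and no conclusion is drawn from the difference. With a separate KO library in each comparison the covariance was 0.293 and, with the KO libraries exchanged, 0.0983; each of these rests on a single KO library per comparison. The covariance depended on which libraries were included. It was -0.157 without WT replicate 1, -0.263 without KO replicate 2 and -0.235 without both, and -0.517 without KO replicate 1 and -0.0251 without WT replicate 2. No sets were simulated for fewer libraries, so these values have no reference.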

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

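The settings without both insulin-poor libraries, with a crossed replicate block and with a replicate block by deposited number were chosen after the values were seen, as was the definition of a list's reversal as a change of sign of its median; the other settings were fixed before the data were examined. Values are log2 fold changes, medians for lists, and the cause of each difference was not tested. List members named in the text were followed through their list only. No gene passed in any of the 3 comparisons under any setting; the lowest adjusted p by limma was 0.135, without WT replicate 2, where 2222 genes of KO+DNMT3A against WT had an unadjusted p under 0.05. The macrophage list kept its direction and call in both comparisons with KO+DNMT3A under every setting in which lists were tested, all but the crossed replicate block, except the estimated correlation. With the estimated correlation 0 lists were called in KO against WT, 0 in KO+DNMT3A against KO and 0 in KO+DNMT3A against WT.

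With a pseudocount of 0.1, 5 lists were called in KO against WT, Slc2a2 turned to 1.05 there, and the covariance of the opposite-change test was -0.404. The cell cycle median of KO+DNMT3A against KO was 0.0339 with no filter, 0.421 with a filter of 5 FPKM and 0.0321 with only the groups compared. Quantile normalization turned Ins2 in KO against WT to -0.0268 and, in KO+DNMT3A against WT, Rptor to -0.174, Dnmt3a to -0.177, Gcg to -0.102 and Mafa to -0.113; median scaling turned Dnmt3a there to -0.188.

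With both insulin-poor libraries left out, a single WT and a single KO library remained, and 5 lists were called in KO against WT. The medians there were 0.146 for duct, 0.172 for stellate and -0.675 for Schwann cells, with Ins1 at 0.241 and Ucn3 at -0.711. In KO+DNMT3A against KO the medians were -0.144 for mature beta cell genes and 0.0469 for Schwann cells. They were 0.12 for ribosomal proteins and 0.635 for mitochondrially encoded genes. Ins1 was at -0.558, Ins2 at -0.888, Gcg at 0.112, Ucn3 at -0.453 and Slc2a2 at -0.501. In KO+DNMT3A against WT the medians were 0.163 for genes repressed in mature beta cells and -0.395 for mature beta cell genes. They were -0.00646 for insulin processing and 0.114 for endothelial cells. Dnmt3a was at -0.206, Ins1 at -0.317, Ins2 at -0.394, Mafa at -0.558, Ucn3 at -1.16 and Slc2a2 at -1.38. The covariance was -0.235 and the correlation -0.562.

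With each library left out in turn, list medians in KO against WT that changed sign ranged as follows, lowest to highest: cytosolic ribosomal proteins -0.471 to 0.0391, genes repressed in mature beta cells -1.17 to 0.0843, Schwann cells -0.147 to 1.67 and stellate cells and fibroblasts -1.65 to 0.361. With each library left out in turn, list medians in KO+DNMT3A against KO that changed sign ranged as follows, lowest to highest: cell cycle -0.328 to 0.126, cytosolic ribosomal proteins -0.333 to 0.235, endothelial cells -0.409 to 0.238, mature beta cell genes -0.144 to 1.7, mitochondrially encoded genes -1.06 to 0.635, Schwann cells -1.21 to 0.0469 and stellate cells and fibroblasts -0.76 to 0.0713. With each library left out in turn, list medians in KO+DNMT3A against WT that changed sign ranged as follows, lowest to highest: endothelial cells -1.08 to 0.114, genes repressed in mature beta cells -1.06 to 0.217, glycolysis -0.613 to 0.281, insulin processing and exocytosis -0.00646 to 1.71 and mature beta cell genes -0.395 to 2.32. Single genes of KO against WT that changed sign ranged over the same settings as Rptor -0.482 to 0.381, Ins1 -4.28 to 3.88, Ins2 -3.53 to 3.77, Slc2a2 -2.27 to 2.17 and Ucn3 -2.33 to 3.36. Single genes of KO+DNMT3A against KO that changed sign ranged over the same settings as Rptor -0.162 to 0.701, Gcg -0.484 to 0.112, Ins1 -0.558 to 7.6, Ins2 -0.888 to 6.41, Ldha -1.44 to 0.601, Slc2a2 -0.501 to 2.28 and Ucn3 -0.453 to 2.79. Single genes of KO+DNMT3A against WT that changed sign ranged over the same settings as Dnmt3a -0.206 to 0.258, Rptor -0.167 to 0.606, Ins1 -0.317 to 6.96, Ins2 -0.394 to 6.15, Mafa -0.558 to 0.828, Slc2a2 -1.38 to 3.06 and Ucn3 -1.16 to 4.53. The number of lists called ranged from 5 to 10 in KO against WT, 6 to 10 in KO+DNMT3A against KO and 6 to 12 in KO+DNMT3A against WT, the covariance from -0.517 to -0.0251 and the correlation from -0.662 to -0.042. Calls of KO against WT were absent without WT replicate 1 for the hormone, repressed, duct, Schwann and ribosomal lists, without WT replicate 2 for the hormone, Schwann, glycolysis, cell cycle and ribosomal lists, without KO replicate 1 for the repressed, stellate, cell cycle and ribosomal lists, and without KO replicate 2 for the hormone, duct and Schwann lists. In KO+DNMT3A against KO the cell cycle was called in none of the 6 fits and the mitochondrially encoded list, as lower, only without KO replicate 1. Calls were also absent there without KO replicate 1 for endothelial cells, without KO replicate 2 for mature beta, stellate, Schwann and ribosomal lists, without KO+DNMT3A replicate 1 for duct, endothelial and ribosomal lists, and without KO+DNMT3A replicate 2 for mature beta, stellate, Schwann and endothelial lists. Those of KO+DNMT3A against WT were absent without WT replicate 1 for the repressed, mature beta, processing, endothelial, stellate and mitochondrially encoded lists, without WT replicate 2 for glycolysis, without KO+DNMT3A replicate 1 for the ribosomal and mitochondrially encoded lists, and without KO+DNMT3A replicate 2 for the repressed, mature beta and glycolysis lists. Lists called with the other sign were stellate cells in KO against WT without WT replicate 1 (adjusted p = 0.0135) and mitochondrially encoded genes in KO+DNMT3A against KO without KO replicate 2 (0.0018). A group left with 1 library was assumed to vary like the others.

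Replicate numbers need not pair the libraries. The deviations of libraries with the same number from their group mean correlated across genes at -0.269 between WT and KO, 0.101 between WT and KO+DNMT3A and 0.318 between KO and KO+DNMT3A. With a replicate block 0 genes passed in each comparison by limma (285, 154 and 391 at an unadjusted p under 0.05), and 7 of 8, 7 of 9 and 9 of 10 list calls were kept; the hormone list of KO against WT had an adjusted p of 0.0606. With a crossed replicate block 0 genes passed in each (276, 178 and 515 at an unadjusted p under 0.05). With a replicate block by deposited number, which groups the libraries numbered 3, the correlations were 0.269, -0.101 and 0.318, 0 genes passed in each (357, 203 and 717 at an unadjusted p under 0.05), and 5 of 8, 8 of 9 and 10 of 10 list calls were kept. Depth limits what could be seen: 1 fragment on 2 kb was worth 2.04 FPKM in WT replicate 1.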

Other observations

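The tests of depth, dilution and cell share for the insulin transcripts were chosen after the values were seen. So were those of all non-endocrine cells moving alike. The latter were changed again after first results, to compare any pair of the lists, and the duct result then turned against that explanation. The tests on second lists of macrophage and duct genes were written down before those genes were looked at. Intervals are 95% ranges of a list's median over 10000 resamplings of its genes. They show the spread between genes, which can move together, not between libraries.

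With all 6 libraries, the lists given here, among them mTOR complex, DNA methylation and Polycomb genes, had no call in any of the 3 comparisons. Lists of glycolysis, the cell cycle, ribosomal proteins and genes repressed in mature beta cells are not among them. Those were called lower in KO and in KO+DNMT3A against WT with the preset correlation, as given above. In KO against WT the median log2 fold change was 0.00 for mTOR complex genes (camera adjusted p = 0.92), -0.07 for the DNA methylation machinery (0.856), 0.01 for Polycomb genes (0.856), 0.147 for imprinted genes (0.856) and -0.10 for genes of immature endocrine cells (0.784), whose mean, 0.376, had the other sign. Metabolic lists had medians of 0.288 for cholesterol synthesis (0.635), -0.15 for fatty acid synthesis (0.856), -0.187 for oxidative phosphorylation (0.134) and 0.003 for lysosome and TFEB targets (0.856), and stress lists of -0.114 for ATF4 targets (0.137), 0.106 for ER folding (0.856) and 0.14 for the interferon response (0.856). Medians of cell cycle inhibitors and immediate early genes were -0.08 (0.856) and -0.05 (0.834). In KO+DNMT3A against KO, 9 of 10 DNA methylation genes were higher (median 0.293, adjusted p = 0.531), as were 16 of 19 imprinted genes (median 0.296, adjusted p = 0.531), beside a median of 0.189 for all genes. Leaving out the insulin-poor libraries gave calls in some of these lists, from fits with a single library in WT, in KO or in both. The ER folding median in KO against WT was 1.16 without KO replicate 2 and 0.437 without both libraries. In KO+DNMT3A against KO it was -0.782 without both. The ATF4 median was -0.591 in KO against WT without WT replicate 1, and -0.405 in KO+DNMT3A against WT without both. Without both, the oxidative phosphorylation median was -0.263 in KO+DNMT3A against KO. In KO+DNMT3A against WT the medians were then 0.405 for genes of immature endocrine cells and -0.256 for lysosome genes. Of the lymphocyte list 0 genes and of the germline list 1 gene were measured, and these lists were not tested.

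Insulin transcripts were far lower in WT replicate 1 and KO replicate 2 than in the other library of the same group. Lower depth is argued against by counting error: the upper 95% Poisson limit of Ins1 was at most 0.747% of the other library. Dilution by mitochondrially encoded genes and Gm42418, Gm26917 and Lars2 is argued against as well, since Ins1 held at most 1.1% of its share in the other library once these were removed. A lower share of beta cells as the whole cause would raise the genes of every other cell type alike. Their list medians instead lay at least 2.24 log2 units apart in each library. Between the KO+DNMT3A libraries, where Ins1 was high in both, non-endocrine lists also lay up to 1.64 log2 units apart. The gap therefore does not exclude a lower share of beta cells together with other changes. Changes within beta cells, several cell types changing at once, handling and RNA quality stay open and were not tested. Mitochondrially encoded genes, listed in advance as a sign of RNA quality, took a larger share in both libraries than in the others. The WT and KO groups hold 1 of these libraries each and KO+DNMT3A holds none. The deposited names of both end in the number 3, as does that of KO+DNMT3A replicate 2, where Ins1 was 100107 FPKM; what the numbers stand for is not stated.

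Macrophage genes were lower in both KO+DNMT3A libraries than in the other 4. In a second list, 9 of 21 measured genes were below all 4 others in both libraries, against a 95th percentile of 1 for random lists. Random lists draw genes independently, while markers of a cell type can move together, so the percentile does not measure chance. These 9 genes were also low, at 0 to 5.30 FPKM in the KO+DNMT3A libraries, where counts are few. Fewer macrophages, or less of their RNA, is a candidate explanation. The stellate list, with 3 of 22 such genes, also exceeded random lists. Depth is argued against: the second list was higher in KO replicate 1, whose depth lies between theirs, by a median of at least 0.6 log2 units. A smaller share of all non-endocrine cells cannot be told apart. In KO+DNMT3A replicate 2 the largest gap between these lists was 0.88 with no intervals apart. In KO+DNMT3A replicate 1 it was 2.28 with intervals apart. That gap lay between duct and macrophage genes, both chosen after their values in these libraries were seen, so it does not decide the question either. Dnmt3a itself is confounded with the group and was not tested. Lentiviral treatment was not tested either: the deposited names of the WT and KO libraries contain GFP, but the labels do not say whether those islets received a control virus.

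Duct genes were higher in WT replicate 1 and KO+DNMT3A replicate 1 than in the other library of the same group. A second duct list did not reach the 95th percentile of random lists set in advance for more duct cells. Its median was at the 94.9th percentile in WT replicate 1 and the 82.7th in KO+DNMT3A replicate 1. The median differences were 0.17 (95% interval over genes -0.47 to 1.19) and 0.42 (-0.26 to 1.24) log2 units. These intervals are wide, so the second list does not exclude more duct cells. More of all non-endocrine cells alike is argued against in both libraries, as far as the spread between genes shows, because the lists changed unequally. The largest gap was 3.46 log2 units in WT replicate 1, between stellate and Schwann cell genes, with intervals apart. It was 1.64 in KO+DNMT3A replicate 1, between duct and macrophage genes, also with intervals apart. The duct list was picked for being high there. Without it, stellate genes (0.83, interval 0.81 to 1.03) and endothelial genes (0.28, 0.02 to 0.5) still lay apart in that library. What raised the duct genes stays open. The labels name no difference between the libraries of a group.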
